A study of Mus musculus with 40 samples.

How the data were processed

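RNA from nucleus accumbens punches of 40 C57BL/6J mice was sequenced, 1 library per mouse, in 8 groups of 5. The groups are intact males and intact females given saline or cocaine, and ovariectomized females carrying placebo or estradiol and given saline or cocaine. Per the labels' protocols, mice were handled for 3 days, cocaine was given at 10 mg/kg per day on days 1 and 7 and at 20 mg/kg per day on days 2 to 6, and left and right punches went into Trizol. The series record places the tissue collection after withdrawal, without a length. The labels name an AmpliSeq kit, 1 shared sequencing lane, and a read number per sample given as 9.4 + 4.7 in units of 1000000, without saying what 4.7 stands for.

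The deposited table holds one value per gene and mouse. Its name says FPKM, but every one of the 40 columns sums to 1000000, so the authors' values are in TPM (transcripts per 1000000, the share of a library's length-adjusted fragments). How FPKM became TPM is not stated. Per the submitters' processing notes, Bowtie2 2.1.0.0, TopHat2 2.0.9, Cufflinks 2.2.0, Cuffdiff 2.2.0, DESeq2 and limma were used with genome build mm10; which tool made the table is not stated. All 40 columns matched a sample and 0 were left over. Groups were taken from the sample titles. In 1 case the code in the description disagrees with the title (69-MS against male cocaine 69); that library was kept under its title and is called the library labelled male cocaine 69 throughout.

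Of 23349 entries, 27 carry a date in place of a gene name, a known effect of spreadsheet software. They cover 25 distinct dates and hold 0.0934% to 0.272% of a library's TPM, and were left out because a date cannot be traced to 1 gene. Of the remaining 23322 gene names, 3463 were at 0 in all libraries. Genes with at least 1 TPM in at least 5 of the 40 libraries were tested, which left 15196. Values were taken as log2(TPM + 0.5). Coordinates and transcript lengths came from the mm10 annotation of GENCODE release M21.

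TPM gives no fragment counts, so the depth of each library is unknown and no counting interval could be computed. A rough scale came from 2661 genes at least 500 bases long that were above 0 in fewer than 20 libraries, where the commonest product of value and length marks a single fragment. By this measure 1 fragment on a transcript of 1 kb was worth 0.0721 to 1.18 TPM depending on the library, with a median of 0.255.

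All 13 comparisons were contrasts of 1 model with a mean for each of the 8 groups (32 residual degrees of freedom), fitted with limma 3.58.1 in R 4.3.3 with the trend and robust options. P-values were adjusted over the 15196 genes by the Benjamini-Hochberg method, with a threshold of 0.05. The comparisons are cocaine against saline in each of the 4 conditions and on average over them, the difference in cocaine response between the sexes and between estradiol and placebo, females against males in saline and in cocaine mice, estradiol against placebo in saline mice, in cocaine mice and on average, and ovariectomized placebo against intact females in saline mice. Each difference is the first-named group minus the second, cocaine minus saline, or estradiol minus placebo. Errors on log2 differences are standard errors of the model, errors on TPM are standard deviations over 5 mice, and intervals on log2 differences are 95% intervals.

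There were 35 gene lists. They cover immediate-early genes, striatal projection neurons, D1 and D2 neurons, dopamine signalling, glutamate receptors and scaffolds, the GABA system, neuropeptides, opioid and cannabinoid receptors, steroid receptors and enzymes, genes escaping X inactivation, Y-linked genes, chromatin modifiers, the circadian clock, glucocorticoid response, interferon response, heat shock, oxidative phosphorylation, cytosolic ribosomal proteins, extracellular matrix and genes of the cocaine literature. The remaining lists hold markers of oligodendrocytes, their precursors, astrocytes, microglia, endothelium, vessel wall and meninges, choroid plexus and ependyma, blood, cortical excitatory neurons, septal and subpallial neurons, hypothalamic and thalamic neurons, cholinergic neurons, interneurons and pituitary hormones. Of their symbols, 7 were found under an older name, among them Drd1 as Drd1a, and 1 (Hbb-bt) was absent. Lists with at least 5 tested members, 34 of the 35, were tested with camera in limma at a preset inter-gene correlation of 0.01, which compares a list with all other genes. The Y-linked list had 4 tested members and was not tested as a list. Beside it stand camera with the correlation estimated from the data and fry. Adjustment was over the 34 lists of a comparison, and single members were also adjusted over the list alone.

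Some comparisons move the median of all tested genes by more than 0.1 on the log2 scale, so list results are given as a relative median: the median log2 difference of the members minus that of all tested genes. A list score per library is the mean log2 value of its members minus the library's median gene. Scores were compared with exact permutation tests within conditions, and over the 4 conditions with 100000 resamples of the treatment labels within conditions, all two-sided, in R. The correlation of the cocaine responses between conditions was computed across genes, with 100 permutations of the treatment labels.

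The genes named are those past the threshold and, where fewer than 10 passed, the 5 with the smallest p in each direction, reported as not passing. Fosb, Arc, Drd1, Drd2, Pdyn, Penk, Tac1, Cartpt, Bdnf and Esr1 were chosen as candidates, and Xist, Ddx3y and Eif2s3y as a check of the sex labels. For each list called, the 4 members with the smallest p serve as examples. The groups, main tests, lists, naming rule and first set of alternatives were fixed before the data were examined. The immediate-early score test and levels of other genes (Slc17a7, Fos, Prl, Gh, Ttr, Rn45s) were picked after values were seen.

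The alternatives tried were pseudocounts of 0.1 and 1, no filter on low values, quantile normalization, TMM scaling, no trend or robust option, the run of animal numbers as a covariate, sample weights from limma's arrayWeights, a fit of only the 20 intact or 20 ovariectomized mice, the library labelled male cocaine 69 placed with male saline, and each library left out in turn. Chosen after seeing the data were fits without the 4 libraries whose median correlation with the others was under 0.93, without those and the library labelled male cocaine 69, with the ribosomal protein share as a covariate, with that covariate and sample weights, list tests with each library left out, and list scores without male cocaine 69. For every comparison, 100 regroupings of the same mice were drawn, the real one included, with seed 1. The code was tested by planting 2-fold and 4-fold differences in 100 genes each, on residuals of the real libraries and on independent normal noise. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.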

Results

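Gene expression was measured in the nucleus accumbens, the ventral striatal region that receives dopamine input and responds to cocaine, in 40 mice after cocaine or saline and withdrawal. The groups were intact males, intact females, and ovariectomized females with placebo or estradiol, each given saline or cocaine, with 5 mice per group. Removing the ovaries takes away the main source of estradiol, and the estradiol group has it replaced. By its title the study concerns why females respond more strongly to cocaine than males. Intact and ovariectomized mice carry separate ranges of animal numbers (61 to 80 and 121 to 140), so surgery and cohort cannot be told apart in any comparison across them.

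Each library held 15276 to 17852 genes above 0, and libraries of the same group correlated with a median of 0.962 (lowest of all pairs 0.843, highest 0.987). Ribosomal protein genes took a share of TPM that differed widely between libraries and moved with the level of the median gene (Pearson r = -0.97, permutation p = 1e-05, the smallest the resamples can give; Spearman rho = -0.92; adjusted p = 3e-05 over 3 relations). The relation held without the 2 libraries farthest out (r = -0.95), within intact mice (r = -0.99) and within ovariectomized mice (r = -0.95). Across all genes, the first principal component held 53.5% of the variance and followed this share (Spearman rho = -0.94). The share averaged 10.5% ± 5.39 (SD, n = 5) in estradiol cocaine mice against 6.29% ± 0.866 in estradiol saline mice, and 4.99% ± 0.384 in intact female cocaine mice. Ovariectomized placebo mice had 8.05% ± 2.29 with saline and 6.83% ± 1.22 with cocaine, while the intact male groups had 6.79% ± 2.40 and 6.80% ± 4.49 and intact female saline mice 5.59% ± 1.69. In 4 libraries the median correlation with the others was under 0.93: male cocaine 67, ovariectomized placebo saline 137, and ovariectomized estradiol cocaine 126 and 134. Their ribosomal protein shares were 14.8%, 11.8%, 18.4% and 13.8%.

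**Figure D1:**
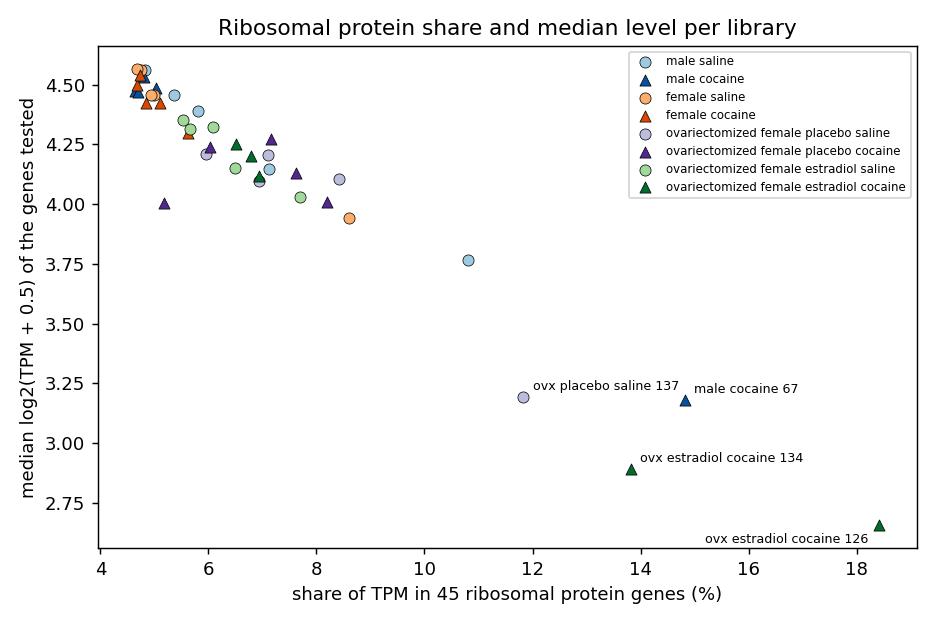
Share of TPM in 45 ribosomal protein genes (horizontal axis, percent) against the median log2(TPM + 0.5) of the tested genes (vertical axis), with 1 point per library, coloured by group. The 4 least correlated libraries, labelled in the plot, lie at 11.8% to 18.4% and have the lowest medians.

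The median of all tested genes was also shifted in several comparisons: by 0.13 for sex in saline mice, 0.19 for sex in cocaine mice, 0.15 for cocaine in placebo females, -0.56 for cocaine in estradiol females, -0.71 for the estradiol by cocaine interaction, 0.23 for estradiol in saline mice, -0.49 for estradiol in cocaine mice and -0.37 for ovariectomized placebo against intact females. Lists are therefore reported by relative median, while single-gene log2 differences and counts above or below 0 keep this shift. Where a list has 2 adjusted p values, the first is from camera with the preset correlation, the second with an estimated one. Fry called no list.

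Females were compared with males in saline mice to find the baseline difference between the sexes. Xist, the RNA that silences 1 X chromosome in female cells, was higher in females by 7.02 ± 0.88 on the log2 scale (216 ± 85.7 against 2.15 ± 3.37 TPM, SD, n = 5; limma adjusted p = 7.53e-06). All 4 genes that were lower lie on the Y chromosome: Eif2s3y, a translation initiation factor (-5.38 ± 0.64, adjusted p = 1.61e-06), Ddx3y, an RNA helicase (-5.16 ± 0.62, adjusted p = 1.61e-06), Kdm5d, a histone demethylase (-4.20 ± 0.50, adjusted p = 1.61e-06) and Uty (-3.66 ± 0.45, adjusted p = 2.63e-06). On mm10, Xist lies on chromosome X from 103460366 to 103483254, Kdm5d on chromosome Y from 897788 to 956786, Eif2s3y from 1010543 to 1028847, Uty from 1096861 to 1245759 and Ddx3y from 1260771 to 1286629. These 5 genes were all that passed of 15196, and 214 had an unadjusted p under 0.05. Genes that escape X inactivation lay above the other genes, with a relative median of 0.54 and 8 of 8 members above 0 (adjusted p = 2.1e-13, adjusted p = 0.0440 with an estimated correlation). Xist was 1 of 1 member called both over all genes and adjusted over the list alone, and Eif2s3x (0.87 ± 0.34), Pbdc1 (0.59 ± 0.25) and Kdm6a (0.77 ± 0.39) did not pass.

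Blood transcripts were lower in saline females than in saline males, with a relative median of -0.93 and 1 of 8 members above 0 (Hbb-b1, a globin, -0.88 ± 0.35; adjusted p = 2.78e-07, adjusted p = 0.0170 with an estimated correlation). Pituitary hormone transcripts had a relative median of 0.79 (adjusted p = 0.00239, adjusted p = 0.0971 with an estimated correlation), and 2 of 5 members passed when adjusted over the list alone: Prl, prolactin (3.57 ± 0.98), and Tshb, the thyrotropin beta chain (1.34 ± 0.48). The pituitary list was not called when the 4 least correlated libraries were left out of the model. Further lists were called only with the preset correlation. Relative medians were below 0 for immediate-early genes, which neurons switch on after activity (-0.29, adjusted p = 6.10e-05), oxidative phosphorylation (-0.38, adjusted p = 3.53e-14; 0.07 with the ribosomal protein share as covariate), ribosomal proteins (-0.38, adjusted p = 1.80e-15), vessel wall and meninges (-0.52, adjusted p = 0.00106), choroid plexus and ependyma (-0.72, adjusted p = 0.0245) and cortical excitatory neurons (-0.86, adjusted p = 1.11e-07). With an estimated correlation these had, in order, adjusted p = 0.825, adjusted p = 0.669, adjusted p = 0.482, adjusted p = 0.825, adjusted p = 0.778 and adjusted p = 0.481. They were above 0 for the GABA system (0.16, adjusted p = 0.0259) and cholinergic neurons (0.24, adjusted p = 0.0245). Each had, with an estimated correlation, adjusted p = 0.825. Ms4a3 (1.38 ± 0.35), B3gnt3 (1.33 ± 0.36), 4833418N02Rik (1.03 ± 0.31) and 1600029I14Rik (-1.94 ± 0.54) had the next smallest p beside Prl and did not pass.

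In cocaine mice, females again had more Xist (5.68 ± 0.88, adjusted p = 0.000642) and less Eif2s3y (-5.08 ± 0.64, adjusted p = 1.41e-05), Ddx3y (-4.72 ± 0.62, adjusted p = 1.88e-05), Kdm5d (-3.75 ± 0.50, adjusted p = 2.55e-05) and Uty (-3.25 ± 0.45, adjusted p = 4.28e-05) than males. Leaving out the library labelled male cocaine 69 gave 7.14, -6.26, -5.83, -4.63 and -4.06, the farthest from 0 of any library left out. These were the 5 genes called by limma, with 207 at an unadjusted p under 0.05. With only the 20 intact mice in the fit limma called 0, with 300 at an unadjusted p under 0.05. The library labelled male cocaine 69 had Xist at the female level, 237 TPM, and Y-linked genes near 0 (Ddx3y 0.318 TPM, Eif2s3y 0.259 TPM). The 9 other male libraries had 0.138 to 8.02, 13.5 to 53.4 and 14.3 to 67.5 TPM of these genes, and the 10 intact females had Xist at 80.6 to 308 TPM. With that library, male cocaine mice averaged 48.2 ± 105 TPM of Xist and 33.5 ± 24.8 TPM of Ddx3y against 215 ± 43.4 and 0.235 ± 0.453 TPM in female cocaine mice.

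**Figure D2:**
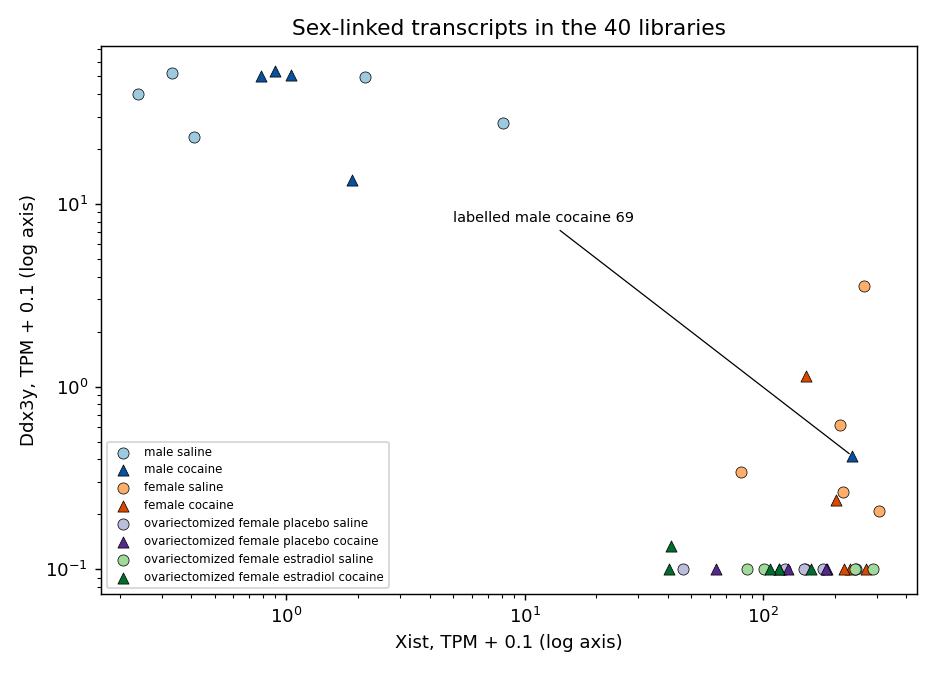
Xist (horizontal axis) against Ddx3y (vertical axis) in the 40 libraries, both as TPM + 0.1 on log axes, coloured by group. The library labelled male cocaine 69 (Xist 237 TPM, Ddx3y 0.318 TPM) lies among the females, apart from the 9 other males.

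Genes that escape X inactivation had a relative median of 0.35 in cocaine females against cocaine males (8 of 8 above 0; Eif2s3x 0.73 ± 0.34; adjusted p = 8.66e-08, adjusted p = 0.173 with an estimated correlation), with 1 member, Xist, called over all genes and adjusted over the list alone. Blood transcripts were lower at -0.62 (S100a8, a neutrophil protein, -2.1 ± 1.03; adjusted p = 6.17e-07, adjusted p = 0.0208 with an estimated correlation). The blood list was not called when the 4 least correlated libraries were left out. Markers of hypothalamic and thalamic neurons lay higher, with a relative median of 0.57 and 10 of 12 members above 0 (adjusted p = 0.000318, adjusted p = 0.173 with an estimated correlation). Of them, 2 passed when adjusted over the list alone: Slc17a6, the vesicular glutamate transporter of these regions (1.59 ± 0.54), and Otp, a hypothalamic transcription factor at 1.76 ± 1.62 TPM in females and listed at 0 in all male cocaine libraries. Oxidative phosphorylation (-0.43, adjusted p = 2.28e-22) and ribosomal proteins (-0.44, adjusted p = 2.37e-26) lay lower, but their relative medians became 0.12 and 0.06 without the 4 libraries. In the same order and with an estimated correlation, the values were adjusted p = 0.347 and adjusted p = 0.173. Relative medians were also called for immediate-early genes (-0.29, adjusted p = 5.43e-05), septal and subpallial neurons (0.35, adjusted p = 0.0487) and cholinergic neurons (0.32, adjusted p = 0.00302). For each of these an estimated correlation gave adjusted p = 0.963. Striatal projection neuron genes had a relative median of -0.16 although their own median (0.03) and mean (0.01) were above 0 (adjusted p = 0.00527, adjusted p = 0.963 with an estimated correlation). Among genes that did not pass, 4930405J17Rik (1.25 ± 0.35), Samd3 (1.44 ± 0.42), Atp6v0c (0.77 ± 0.22), Otp and 4930452G13Rik (-1.22 ± 0.34) had the smallest p.

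Cocaine was compared with saline in males to describe the male response. Markers of choroid plexus and ependyma, the tissues lining the ventricles, lay lower after cocaine. The relative median was -0.70, with 11 of 13 members below 0. Examples are Foxj1, a regulator of cilia (-1.04 ± 0.39, n = 5 per group), Dynlrb2 (-1.55 ± 0.66), Rarres2 (-0.88 ± 0.41) and Tmem212 (-1.75 ± 0.85). The call rested on the preset correlation (adjusted p = 4.04e-06, adjusted p = 0.285 with an estimated correlation). Markers of vessel wall and meninges had a relative median of -0.34 (2 of 14 above 0, Tagln -0.64 ± 0.47; adjusted p = 0.0489, adjusted p = 0.941 with an estimated correlation). The list of X-inactivation escape genes had a relative median of 0.24 (8 of 8 above 0, Xist 1.44 ± 0.88; adjusted p = 0.0120, adjusted p = 0.941 with an estimated correlation), a direction to which the library labelled male cocaine 69, with female levels of these genes, contributes. Without it and the 4 least correlated libraries the relative median was 0.21 and the list was not called. Fosb, a marker of repeated cocaine, differed by 0.43 (95% interval -0.48 to 1.34), Bdnf, a neuronal growth factor, by 0.70 (-0.55 to 1.95), and the dopamine receptor genes Drd1 and Drd2 by -0.09 (-0.70 to 0.52) and -0.27 (-1.03 to 0.48).

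In males limma called 0 of 15196 genes, and 155 had an unadjusted p under 0.05, reached in 61 of 100 regroupings. Without the 4 least correlated libraries 0 genes passed and 2359 had an unadjusted p under 0.05, with ribosomal proteins at a relative median of -0.59 (adjusted p = 3.41e-34, adjusted p = 0.190 with an estimated correlation). The smallest p values belonged to Mir341 (117 ± 93.1 TPM with cocaine) and Snora65 (43.6 ± 19.6 TPM), both listed at 0 in all saline males, Prm1 (2.21 ± 1.72 TPM with saline, listed at 0 with cocaine), 1700022P22Rik (1.32 ± 0.43), Gm11762 (1.27 ± 0.44), Snord15b (4.31 ± 1.48), Atp6v0c, a subunit of the vesicle proton pump (-0.79 ± 0.22), Mfap2 (-1.10 ± 0.34), Macrod1 (-0.85 ± 0.27) and Rplp2-ps1 (-2.09 ± 0.67).

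In intact females, markers of striatal projection neurons, the main output cells of the accumbens, lay lower after cocaine: 24 of 24 members were below 0, with a relative median of -0.34. Examples are Penk, the enkephalin precursor (-0.47 ± 0.25, n = 5 per group), Ppp1r1b, which encodes the dopamine-regulated phosphoprotein DARPP-32 (-0.43 ± 0.25), and Adora2a, the adenosine receptor of D2 neurons (-0.43 ± 0.27). Markers of cortical excitatory neurons moved the other way, with a relative median of 0.89 and 14 of 16 above 0 (Neurod1 1.60 ± 0.58, Nrn1 1.75 ± 0.79, Tbr1 1.60 ± 0.93, Tshz3 0.58 ± 0.37). Pituitary hormone transcripts lay lower at -1.04 (Tshb -1.02 ± 0.48, Prl -1.94 ± 0.98, Gh, growth hormone, -1.65 ± 0.97). Camera gave adjusted p = 1.67e-13 for the striatal list (adjusted p = 0.567 with an estimated correlation), adjusted p = 8.08e-10 for the cortical list (adjusted p = 0.489 with an estimated correlation) and adjusted p = 0.00108 for the pituitary list (adjusted p = 0.163 with an estimated correlation). The striatal score averaged 3.64 ± 0.19 in saline and 3.29 ± 0.12 in cocaine females (SD, n = 5; difference -0.35, exact permutation p = 0.0317, adjusted p = 0.190 over 12 such tests). Slc17a7, the cortical vesicular glutamate transporter, ranged from 5.81 to 135 TPM in saline and from 14.9 to 622 TPM in cocaine females.

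Dopamine signalling genes (relative median -0.26, 4 of 18 above 0; Th -0.48 ± 0.33; adjusted p = 0.000328), D1 neuron genes (-0.26, adjusted p = 0.0135) and D2 neuron genes (-0.27, adjusted p = 0.00461) share members with the striatal list. All of these had, with an estimated correlation, adjusted p = 0.856. Oligodendrocyte genes, which make myelin (-0.18, 2 of 16 above 0; Opalin -0.43 ± 0.25; adjusted p = 0.000622), and ribosomal proteins (-0.14, adjusted p = 5.76e-05; 0.05 with array weights) also lay lower. Respectively, with an estimated correlation, the lists had adjusted p = 0.856 and adjusted p = 0.9995. Immediate-early genes lay higher (0.16, 20 of 24 above 0; Nr4a2 0.94 ± 0.80, Fos 0.63 ± 0.58; adjusted p = 0.0135), as did heat shock genes (0.11, 12 of 16 above 0; adjusted p = 0.00262). With an estimated correlation these had, in order, adjusted p = 0.9995 and adjusted p = 0.856. The immediate-early score differed by 0.18 (exact permutation p = 0.587, adjusted p = 0.724 over 12 tests). Of the heat shock list, 1 member passed when adjusted over the list alone, the chaperone Hspa1b (1.52 ± 0.45), and 0 over all genes. Bdnf differed by 1.33 (95% interval 0.08 to 2.58, not adjusted; adjusted p = 1) and Fosb by 0.20 (-0.71 to 1.11). Over all genes limma called 0, with 145 at an unadjusted p under 0.05 and the smallest adjusted p = 0.363 for 4930405J17Rik (1.67 ± 0.35). Next in p and also not passing were 4930480K15Rik (1.49 ± 0.39), AY074887 (1.5 ± 0.39), 1700003F12Rik (1.96 ± 1.11 TPM with cocaine, listed at 0 with saline) and Speer4a (1.11 ± 0.32) among the higher, and 1700101I11Rik (-1.23 ± 0.34), 3110045C21Rik (-1.24 ± 0.35), Ms4a3 (-1.17 ± 0.35), Klhl35 (-1.06 ± 0.34) and Ccno (-0.87 ± 0.28) among the lower.

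The difference between the female and male responses asks whether cocaine acts differently in the sexes. Pituitary hormone transcripts differed, with a relative median of -1.49 (Tshb -1.77 ± 0.68, Prl -3.52 ± 1.39, Gh -1.44 ± 1.37), and this call held with an estimated correlation (adjusted p = 0.000282, adjusted p = 0.0476 with an estimated correlation). Tshb and Prl were the 2 of 5 that passed adjusted over the list alone. In TPM, Prl was 16.1 ± 14.6 in saline and 5.81 ± 10.6 in cocaine females, 0.422 ± 0.897 in saline and 2.18 ± 1.83 in cocaine males. Of the cocaine females, 80 had 24.7 TPM and the 4 others 0 to 2.93 TPM. Leaving out the 4 least correlated libraries ended the call (-0.97, adjusted p = 0.401). Striatal projection neuron genes went lower in females than in males (relative median -0.26, 22 of 24 below 0; Tac1, the substance P precursor, -0.32 ± 0.33; adjusted p = 0.000282), and cortical genes higher (0.64, 15 of 16 above 0; adjusted p = 0.00639). Each had, with an estimated correlation, adjusted p = 0.965. Also called were choroid plexus and ependyma (0.64, adjusted p = 0.00766), septal and subpallial neurons (0.36, Zic2 1.42 ± 0.72; adjusted p = 0.00135), heat shock (0.09, adjusted p = 0.0477) and X-inactivation escape genes (-0.21, adjusted p = 0.0439). For each of these an estimated correlation gave adjusted p = 0.965. The last again rests in part on the library labelled male cocaine 69. No gene passed by limma (0 of 15196), with 101 at an unadjusted p under 0.05. Those with the smallest p, none passing, were in the upward direction Prm1 (listed at 0 in cocaine males), 4930480K15Rik (1.86 ± 0.55), 4930405J17Rik (1.53 ± 0.49), Pmaip1 (1.57 ± 0.51) and 1700030L20Rik (1.66 ± 0.56). In the downward direction they were Ms4a3 (-1.74 ± 0.49), 1700102H20Rik (-1.91 ± 0.68), Gm7334 (-2.44 ± 0.90), A330069E16Rik (-1.28 ± 0.47) and Snord22 (-5.76 ± 2.1).

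In ovariectomized females with placebo, which lack ovarian estradiol, striatal projection neuron genes again lay lower after cocaine (relative median -0.27, 6 of 24 above 0; Ppp1r1b -0.43 ± 0.25, n = 5 per group; adjusted p = 7.58e-06), as did D2 neuron genes (-0.29, adjusted p = 0.0269). All of these had, with an estimated correlation, adjusted p = 0.693. The striatal score differed by -0.29 (exact permutation p = 0.159, adjusted p = 0.552 over 12 tests). Oligodendrocyte genes (-0.33, 1 of 16 above 0; Opalin -0.43 ± 0.25, Hapln2 -0.46 ± 0.28; adjusted p = 6.05e-10) and microglial genes (-0.27; Cd68 -0.29 ± 0.20; adjusted p = 4.51e-05) lay lower. An estimated correlation gave, in that order, adjusted p = 0.278 and adjusted p = 0.118. Blood transcripts were also lower (-0.57; S100a8 -2.06 ± 1.03; adjusted p = 7.58e-06, adjusted p = 0.0520 with an estimated correlation). Esr1, the estrogen receptor alpha gene, was at 2.35 ± 0.884 TPM with cocaine and 0.843 ± 0.480 TPM with saline (1.11 ± 0.40, 95% interval 0.29 to 1.93, adjusted p = 0.996). Oxidative phosphorylation (-0.35, adjusted p = 5.06e-16; 0.03 with the ribosomal protein share as covariate), ribosomal proteins (-0.36, adjusted p = 7.81e-17), glucocorticoid response (-0.25, adjusted p = 0.00314) and choroid plexus and ependyma (-0.48, adjusted p = 0.0351) lay lower. Respectively, an estimated correlation gave adjusted p = 0.660, 0.511, 0.693 and 0.693. Glutamate receptors and scaffolds (0.12, 27 of 30 above 0; Grin3a 0.68 ± 0.38; adjusted p = 0.0285) and the GABA system (0.20, adjusted p = 0.0173) lay higher. Each had, with an estimated correlation, adjusted p = 0.875. Without the 4 least correlated libraries oxidative phosphorylation and microglia were not called, ribosomal proteins were at -0.05, and striatal genes remained called at -0.31 (adjusted p = 2.24e-12, adjusted p = 0.280 with an estimated correlation). For vessel wall and meninges the relative median was -0.14 while the members' own median was 0.01 (adjusted p = 0.0334, adjusted p = 0.875 with an estimated correlation). Among single genes limma called 0, with 125 at an unadjusted p under 0.05. None of the genes with the smallest p passed: 4930529F24Rik (1.48 ± 0.34), Dlx6as2 (1.11 ± 0.39), Rxfp3, a relaxin-family receptor (1.00 ± 0.36), Cpne7 (1.02 ± 0.37) and Esr1 were higher, AW112010 (-1.12 ± 0.35), Dmkn (-1.10 ± 0.35) and Cldn26 (-1.16 ± 0.39) lower, and Rbp2 (1.17 ± 0.701 TPM with saline) and Hist1h4j (1.49 ± 1.46 TPM) were listed at 0 with cocaine.

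With estradiol replaced, immediate-early genes lay higher after cocaine, with a relative median of 0.52 (Junb 0.80 ± 0.39, Egr4 0.51 ± 0.42, Nr4a1 0.46 ± 0.40, n = 5 per group; adjusted p = 4.90e-06, adjusted p = 0.472 with an estimated correlation). Of the members 10 of 24 were above 0, as was the mean (0.03), while their own median was -0.04. Their score averaged -0.73 ± 0.20 with saline and -0.09 ± 0.40 with cocaine, and 4 of 5 cocaine libraries lay above the highest saline library (difference 0.64, exact permutation p = 0.0159, adjusted p = 0.190 over 12 tests). GABA system genes lay lower at -0.40, with 18 of 18 below 0 (Gabrb2 -1.20 ± 0.35 and Gabra3 -1.19 ± 0.38, receptor subunits; adjusted p = 0.00438, adjusted p = 0.923 with an estimated correlation). Of these 18, 15 passed adjusted over the list alone and 0 over all genes, where the median gene was at -0.56 and 41.7% of all genes had an unadjusted p under 0.05. Without the 4 least correlated libraries, 2 of which are in this group, these were the only lists called, at 0.71 (adjusted p = 2.65e-22) and -0.20 (adjusted p = 0.0432). Their values with an estimated correlation were adjusted p = 0.0504 and adjusted p = 0.906.

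Oxidative phosphorylation (1.04, 40 of 40 above 0; adjusted p = 7.68e-41) and ribosomal proteins (1.10, 38 of 45 above 0; adjusted p = 1.63e-33) lay higher. For each of these an estimated correlation gave adjusted p = 0.0837. Choroid plexus and ependyma (1.07, adjusted p = 3.77e-05) and pituitary hormones (1.09, adjusted p = 0.000498) lay higher as well. In the same order and with an estimated correlation, the values were adjusted p = 0.140 and adjusted p = 0.0547. For 4 more lists the relative median was above 0 and the mean or the median itself was below 0: neuropeptides (0.50, median -0.06; adjusted p = 7.94e-05), interferon response (0.46, median -0.10; adjusted p = 0.00438), microglia (0.42, median -0.14; adjusted p = 0.00438) and blood (0.89, mean -0.10; adjusted p = 0.00560). Taken in order, the values with an estimated correlation were adjusted p = 0.0547, adjusted p = 0.472, adjusted p = 0.213 and adjusted p = 0.190. Limma called 0 genes, and 6335 had an unadjusted p under 0.05, as many as in 14 of 100 splits of the libraries (highest other 8543), with the smallest adjusted p = 0.0946, shared by the genes named here. Higher were Fam26f (1.44 ± 0.39), Ppp1r14a (1.37 ± 0.37), BC051226 (1.09 ± 0.30), Jsrp1 (1.12 ± 0.32) and Ffar3 (1.38 ± 0.40), and lower were 9430037G07Rik (-1.11 ± 0.28), Zpbp (-1.04 ± 0.26), Znf41-ps (-1.03 ± 0.28), Gm3985 (-1.26 ± 0.34) and Tceanc (-1.04 ± 0.29). Leaving out estradiol cocaine 128, 136 or 140 raised the count to 3624, 6105 and 5898, and without the 4 libraries 0 passed and 329 had an unadjusted p under 0.05.

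The estradiol by cocaine interaction compares the cocaine responses of estradiol and placebo females. GABA system genes responded lower with estradiol (relative median -0.62, 17 of 18 below 0; Gabra3 -1.70 ± 0.54; adjusted p = 0.00222, adjusted p = 0.857 with an estimated correlation), and 12 of 18 passed adjusted over the list alone against 0 over all genes, of which 31.3% had an unadjusted p under 0.05. Glutamate receptors and scaffolds also did (-0.31, 30 of 30 below 0; Grin3a -1.67 ± 0.54; adjusted p = 0.0301, adjusted p = 0.857 with an estimated correlation). Oligodendrocyte genes had a relative median of 0.62 with the median itself at -0.10 (Opalin 1.09 ± 0.35; adjusted p = 0.000758), and immediate-early genes 0.46 with the median itself at -0.26 (adjusted p = 0.00856). An estimated correlation gave, in that order, adjusted p = 0.677 and adjusted p = 0.857. Without the 4 libraries the GABA, oligodendrocyte and immediate-early lists were at -0.30 (adjusted p = 0.00212), 0.43 (adjusted p = 1.58e-07) and 0.76 (adjusted p = 5.82e-11). Here, with an estimated correlation, the values were adjusted p = 0.864, adjusted p = 0.864 and adjusted p = 0.679. Esr1 differed by -1.66 (95% interval -2.81 to -0.50, not adjusted) beside a median gene at -0.71, and did not pass (limma adjusted p = 0.156).

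Another 9 lists had relative medians above 0 in the interaction. Among them were oxidative phosphorylation (1.42, adjusted p = 4.49e-39), ribosomal proteins (1.48, adjusted p = 1.98e-34) and blood (1.54, adjusted p = 0.000201). All of these had, with an estimated correlation, adjusted p = 0.0811. Microglia (0.79, adjusted p = 0.000252), pituitary hormones (1.64, adjusted p = 0.00180) and choroid plexus and ependyma (1.57, adjusted p = 0.000150) were above 0 as well. With an estimated correlation these had, in order, adjusted p = 0.0811, adjusted p = 0.0811 and adjusted p = 0.156. For neuropeptides (0.35, median -0.36; adjusted p = 0.0307), interferon response (0.42, median -0.30; adjusted p = 0.0142) and vessel wall and meninges (0.44, median -0.28; adjusted p = 0.0178) the median itself was below 0. Under an estimated correlation, and in the same order, these gave adjusted p = 0.355, adjusted p = 0.725 and adjusted p = 0.857. At the level of single genes the limma count was 0, with 4753 at an unadjusted p under 0.05 (reached in 12 of 100 splits, highest other 8207; 270 without the 4 libraries) and the smallest adjusted p = 0.156. That value was shared by Smim5 (2.31 ± 0.56), Hist3h2ba (1.5 ± 0.38), 1700047M11Rik (1.11 ± 0.29), BC033916 (2.04 ± 0.55) and Ppp1r14a (1.89 ± 0.53). It was shared below 0 by Ralyl (-1.5 ± 0.36), Camk2d, a calcium-dependent kinase (-2.12 ± 0.55), Mgat4c (-1.48 ± 0.39), Rxfp3 (-1.96 ± 0.51) and Unc5d (-1.95 ± 0.53).

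Estradiol was compared with placebo in saline mice to show the hormone's effect without drug. GABA system genes lay higher with estradiol (relative median 0.41, 17 of 18 above 0; Gad2, a GABA-synthesizing enzyme, 0.93 ± 0.39, n = 5 per group; adjusted p = 0.000253, adjusted p = 0.70 with an estimated correlation). Cholinergic markers (0.46, 9 of 9 above 0; Slc5a7, the choline transporter, 0.97 ± 0.44; adjusted p = 0.00289) and astrocyte markers (0.29, 14 of 14 above 0; Slc1a3 0.73 ± 0.40; adjusted p = 0.0191) were higher too. In the same order and with an estimated correlation, the values were adjusted p = 0.70 and adjusted p = 0.748. Oligodendrocyte genes lay lower (-0.53, 3 of 16 above 0; Opalin -0.71 ± 0.25, Mog -0.45 ± 0.24; adjusted p = 9.72e-09, adjusted p = 0.435 with an estimated correlation). Oxidative phosphorylation (-0.48, adjusted p = 1.92e-17; 0.03 with the ribosomal protein share as covariate), ribosomal proteins (-0.54, adjusted p = 3.53e-18), choroid plexus and ependyma (-0.83, Foxj1 -1.01 ± 0.39; adjusted p = 0.000234), vessel wall and meninges (-0.35, Tagln -1.03 ± 0.47; adjusted p = 0.00118) and pituitary hormones (-0.51, adjusted p = 0.0245) lay lower. In order, an estimated correlation gave adjusted p = 0.474, 0.435, 0.435, 0.70 and 0.435. Lists whose relative median was below 0 with the median itself above 0 were interferon response (-0.14 and 0.09; adjusted p = 0.0263), microglia (-0.21 and 0.02; adjusted p = 0.0191) and endothelium (-0.21 and 0.02; adjusted p = 0.0145). An estimated correlation gave, in that order, adjusted p = 0.729, adjusted p = 0.474 and adjusted p = 0.763. By limma 0 genes passed, with 377 at an unadjusted p under 0.05. Genes with the smallest p, not passing, were Ralyl (0.93 ± 0.25), Rasgrf2 (1.23 ± 0.36), D4Ertd617e (2.07 ± 0.62), Gm2897 (1.07 ± 0.34), Vwc2l (1.17 ± 0.38), Ak8 (-0.90 ± 0.26), Hrct1 (-1.09 ± 0.33), 1700047M11Rik (-0.66 ± 0.21), Smim5 (-1.23 ± 0.40) and Rbp4, the retinol-binding protein (-0.75 ± 0.24).

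In cocaine mice, estradiol went with higher oxidative phosphorylation genes (relative median 0.92, 40 of 40 above 0; Ndufc1 0.69 ± 0.30; adjusted p = 3.50e-46), ribosomal proteins (0.96, adjusted p = 1.45e-36) and blood transcripts (0.81, adjusted p = 9.77e-06). Each had, with an estimated correlation, adjusted p = 0.0461. Of the blood list, 2 members passed adjusted over the list alone, the globins Hbb-b1 (1.02 ± 0.35) and Hbb-bs (0.90 ± 0.33). Microglia (0.60, Tyrobp 0.68 ± 0.32; adjusted p = 6.99e-05), pituitary hormones (1.08, adjusted p = 0.00172) and neuropeptides (0.53, mean -0.03; adjusted p = 0.000845) also held with an estimated correlation. For each of these an estimated correlation gave adjusted p = 0.0461. None of these 6 was called without the 4 least correlated libraries, where the relative medians of the first 2 were -0.07 and -0.06. Immediate-early genes were called in both settings, with a relative median of 0.30 but a median of -0.19 (adjusted p = 0.00827, adjusted p = 0.952 with an estimated correlation), and 0.44 without the 4 libraries (adjusted p = 6.51e-14, adjusted p = 0.327 with an estimated correlation). Glucocorticoid response was as well (0.21, median -0.28; adjusted p = 0.0435, adjusted p = 0.948 with an estimated correlation; 0.18 without the 4, adjusted p = 0.459 with an estimated correlation there). The remaining lists were glutamate receptors and scaffolds (-0.18, 30 of 30 below 0; adjusted p = 0.0333), interferon response (0.27, median -0.22; adjusted p = 0.0435) and choroid plexus and ependyma (0.34, median -0.15; adjusted p = 0.00172). Under an estimated correlation, and in the same order, these gave adjusted p = 0.952, adjusted p = 0.948 and adjusted p = 0.326. The limma count of called genes was 0, with 2385 at an unadjusted p under 0.05 (reached in 41 of 100 splits, highest other 8369) and 153 without the 4 libraries. BC033916 (1.49 ± 0.39), Hist3h2ba (0.98 ± 0.27), Rpain (0.75 ± 0.23), Defb6 (2.02 ± 0.65), Jsrp1 (1.01 ± 0.32), Kcnrg (-1.26 ± 0.31), Gm7120 (-1.20 ± 0.33), Gm20199 (-1.08 ± 0.31), Pcdhga1 (-1.15 ± 0.33) and Olfr543 (-1.08 ± 0.31) had the smallest p and did not pass. Esr1 differed by -1.02 (95% interval -1.83 to -0.20).

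Ovariectomized placebo females, again with library 137 included, were set against intact females, both given saline. Loss of the ovaries cannot be told apart from the cohort here. Esr1 was at 0.843 ± 0.480 TPM after ovariectomy and 3.19 ± 1.28 TPM in intact females (-1.47 ± 0.40, n = 5 per group, adjusted p = 0.247). It was 1 of 2 members of 13 in the steroid receptor list that passed adjusted over the list alone, and 0 did over all genes. Endothelial genes lay lower (relative median -0.47, 12 of 12 below 0), and 7 passed adjusted over the list alone, such as Tek (-1.47 ± 0.41) and Flt1 (-1.55 ± 0.45), receptors for vessel growth factors, Ly6c1 (-0.86 ± 0.26) and Slco1a4 (-1.42 ± 0.46). The endothelial call had adjusted p = 0.000791, and adjusted p = 0.955 with an estimated correlation. Blood transcripts were higher (0.89, 8 of 8 above 0; Hbb-b1 0.81 ± 0.35, S100a8 2.24 ± 1.03; adjusted p = 2.89e-06, adjusted p = 0.0326 with an estimated correlation), and 1, S100a9, passed adjusted over the list alone. S100a9 stood at 7.66 ± 10.6 TPM and was listed at 0 in all intact saline females. Prl was at 0.256 ± 0.573 TPM and Gh at 0.332 ± 0.743 TPM, against 16.1 ± 14.6 and 8.0 ± 7.33 TPM in intact females.

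Chromatin modifiers lay lower in ovariectomized mice (-0.15, 27 of 28 below 0, median gene -0.37, Hdac6 -1.07 ± 0.35, Kmt2a -1.14 ± 0.39, adjusted p = 0.0122). Glutamate receptors and scaffolds (-0.25, adjusted p = 0.0453) and the GABA system (-0.25, adjusted p = 0.0429) did too. Each had adjusted p = 0.955 with an estimated correlation. Oxidative phosphorylation (0.95, 40 of 40 above 0; adjusted p = 1.43e-31), ribosomal proteins (0.87, adjusted p = 4.17e-29), microglia (0.55, Trem2 0.68 ± 0.28; adjusted p = 4.93e-05) and oligodendrocytes (0.37, adjusted p = 0.00343) lay higher. In order, an estimated correlation gave adjusted p = 0.178, 0.177, 0.105 and 0.955. Vessel wall and meninges (0.83, adjusted p = 0.0122), choroid plexus and ependyma (1.12, Kcnj13 1.68 ± 0.60; adjusted p = 0.00343) and cortical excitatory neurons (0.73, 11 of 16 above 0; adjusted p = 0.0122) were higher as well. Of the cortical list 1 member, Rasgrf2 (-1.24 ± 0.36), passed adjusted over the list alone in the other direction. An estimated correlation gave, in that order, adjusted p = 0.955, adjusted p = 0.539 and adjusted p = 0.955. Of 15196 genes limma called 0, with 2927 (19.3%) at an unadjusted p under 0.05, reached in 6 of 100 splits (highest other 5869), and the smallest adjusted p = 0.247. Higher without passing were Ddah2 (1.09 ± 0.25), Snord15b (6.5 ± 1.48), 2010001M06Rik (1.28 ± 0.32), S100a9 and Rnu12 (5.51 ± 1.40), and lower were Gm15328 (-1.92 ± 0.43), 1700028J19Rik (-1.42 ± 0.32), D4Ertd617e (-2.47 ± 0.62), Gm1078 (-1.06 ± 0.27) and Arhgap36 (-2.04 ± 0.52).

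Averaged over the 4 conditions, camera with the preset correlation called immediate-early genes higher and striatal projection neuron genes lower after cocaine. The immediate-early list had a relative median of 0.27 with 20 of 24 above 0, among them Fos (0.64 ± 0.29), Npas4 (0.38 ± 0.25), Nr4a1 (0.33 ± 0.20) and Fosl2 (0.31 ± 0.22), transcription factors induced by neuronal activity. The striatal list had a relative median of -0.19 with 24 of 24 below 0, such as Adora2a (-0.35 ± 0.13), Sh3rf2 (-0.47 ± 0.19) and Penk (-0.29 ± 0.12). Both had adjusted p = 5.57e-14, and adjusted p = 0.448 with an estimated correlation. By library score the mean difference was 0.27 for immediate-early genes (95% interval 0.05 to 0.48, permutation p = 0.0196, adjusted p = 0.0640 over 5 lists) and -0.18 for striatal genes (-0.33 to -0.03, permutation p = 0.0256, adjusted p = 0.0640). Without the 4 libraries these were 0.31 (permutation p = 0.0143, adjusted p = 0.0480) and -0.20 (permutation p = 0.0192, adjusted p = 0.0480). Camera had called all 5 here, so both adjustments are too lenient. Within conditions the immediate-early difference was 0.13 in males, 0.18 in females, 0.12 with placebo and 0.64 with estradiol, and the striatal one -0.08, -0.35, -0.29 and 0.01. In order, these had exact p = 0.230, 0.587, 0.540 and 0.0159, then 0.571, 0.0317, 0.159 and 0.952 (smallest adjusted p = 0.190 over all 12). Without the library labelled male cocaine 69 the male differences were 0.08 (exact p = 0.444) and -0.03 (exact p = 0.833), and the means over the conditions 0.25 and -0.16 (both adjusted p = 0.0975).

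**Figure D3:**
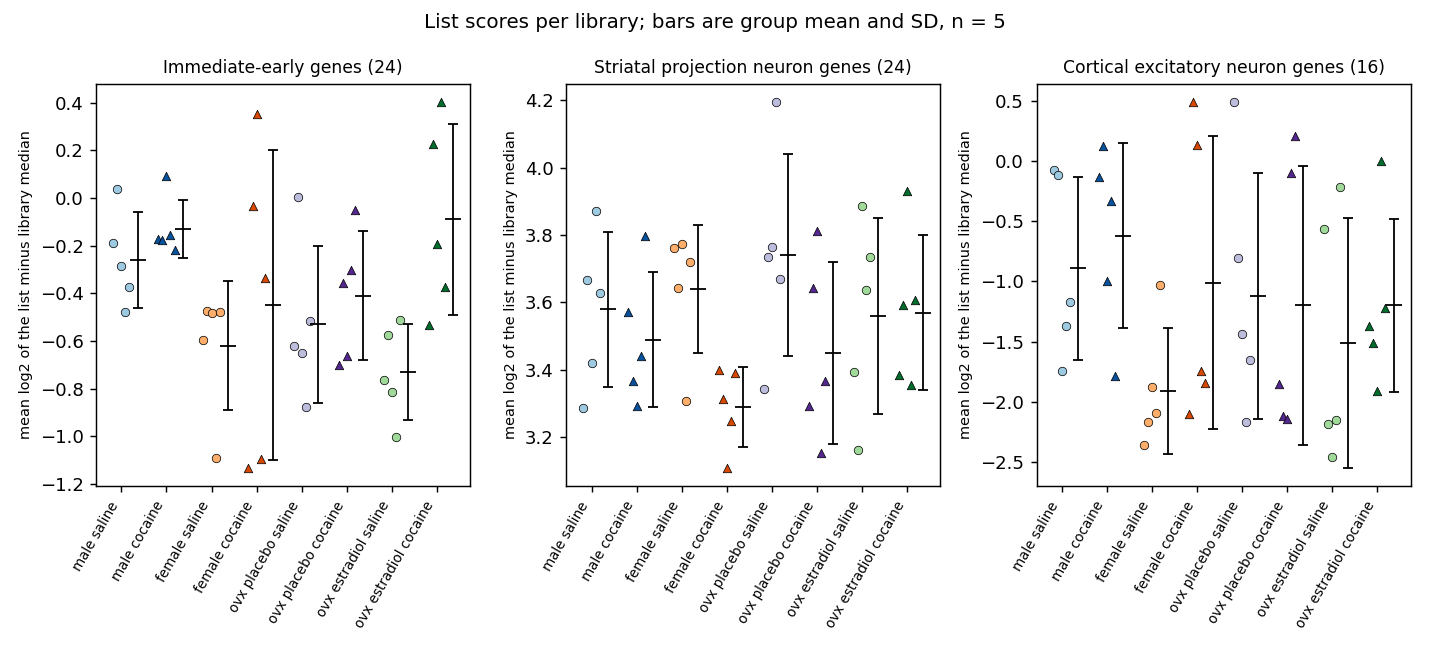
Scores of 3 lists per library (mean log2 of the members minus the library's median gene, vertical axes) by group, with points for libraries and bars for group mean and SD, n = 5. Immediate-early scores are highest relative to saline in estradiol cocaine mice (-0.09 against -0.73), striatal scores lowest in female cocaine mice (3.29), and cortical scores vary most within groups.

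Dopamine signalling (-0.16, Ppp1r1b -0.29 ± 0.13, Rgs4 -0.36 ± 0.17; adjusted p = 1.83e-05), D2 neuron (-0.15, 8 of 8 below 0; adjusted p = 0.000180), D1 neuron (-0.06, Drd1 -0.33 ± 0.15; adjusted p = 0.0404), cholinergic (-0.17, Chat -0.35 ± 0.19; adjusted p = 0.0119) and oligodendrocyte genes (-0.09, Mbp, myelin basic protein, -0.32 ± 0.15; adjusted p = 0.000332) lay lower over the 4 conditions. Respectively, an estimated correlation gave adjusted p = 0.448, 0.448, 0.691, 0.691 and 0.520. Only with estradiol did scores rise after cocaine for D2 (2.05 to 2.21), D1 (1.81 to 1.89) and oligodendrocyte genes (2.86 to 3.19). Cortical excitatory neuron genes lay higher (0.39, 12 of 16 above 0; Neurod1 0.56 ± 0.29; adjusted p = 3.48e-06, adjusted p = 0.448 with an estimated correlation), with a score difference of 0.35 (permutation p = 0.233; within conditions 0.27, 0.89, -0.09 and 0.31, exact p = 0.603, 0.190, 0.921 and 0.579). Neuropeptides were called (0.11, Adcyap1 0.62 ± 0.30; adjusted p = 3.11e-05, adjusted p = 0.0722 with an estimated correlation). Oxidative phosphorylation (0.18, adjusted p = 9.68e-15) and ribosomal proteins (0.12, adjusted p = 0.000289) were too, but turned to -0.13 and -0.17 without the 4 libraries. In order, an estimated correlation gave adjusted p = 0.448 and 0.927. Hypothalamic and thalamic markers had a relative median of 0.10 with a median of -0.01 (adjusted p = 0.0404, adjusted p = 0.448 with an estimated correlation). Gene by gene, limma called 0, with 167 at an unadjusted p under 0.05 and 424 without the 4 libraries. The smallest p values, none passing, belonged to 4930529F24Rik (0.65 ± 0.17), 4930405J17Rik (0.59 ± 0.17), Speer4a (0.49 ± 0.16), 6330415B21Rik (0.58 ± 0.20), Fkbp1b (0.34 ± 0.13). On the lower side they were Slc11a1, a phagocyte metal transporter (-0.45 ± 0.13), Cd44 (-0.47 ± 0.14), Theg (-0.64 ± 0.20), Hpca, the calcium sensor hippocalcin (-0.32 ± 0.10), and Slc22a3 (-0.48 ± 0.15). Fosb differed by 0.13 (95% interval -0.32 to 0.59), Arc by 0.27 (-0.20 to 0.75), Bdnf by 0.57 (-0.06 to 1.20), Pdyn by -0.14 (-0.55 to 0.27) and Tac1 by -0.10 (-0.34 to 0.13).

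Estradiol averaged over both treatments went with lower oligodendrocyte genes (relative median -0.18, 1 of 16 above 0; Mbp -0.47 ± 0.21, Mog -0.34 ± 0.17; adjusted p = 1.03e-05) and lower endothelial genes (-0.17, 12 of 12 below 0; Esam -0.51 ± 0.22; adjusted p = 0.00165). In order, an estimated correlation gave adjusted p = 0.565 and 0.643. Oligodendrocyte scores were lower with estradiol in saline mice (2.86 against 3.38) but higher in cocaine mice (3.19 against 2.96). Cholinergic markers lay higher (0.27, Lhx8 0.48 ± 0.34; adjusted p = 1.66e-05), as did neuropeptides (0.11, Nts, neurotensin, 0.85 ± 0.36; adjusted p = 0.000385) and D1 neuron genes (0.12, adjusted p = 0.0313). With the correlation estimated, they had adjusted p = 0.565, 0.195 and 0.643. Oxidative phosphorylation (0.21, adjusted p = 4.24e-14) and ribosomal proteins (0.18, adjusted p = 1.07e-07) lay higher but turned to -0.12 and -0.14 without the 4 libraries. Respectively, an estimated correlation gave adjusted p = 0.565 and 0.643. Hypothalamic and thalamic markers had 0.20 (adjusted p = 0.0499, adjusted p = 0.565 with an estimated correlation). In 3 lists the median itself was below 0: glucocorticoid response (0.09 and -0.01; adjusted p = 0.00152), microglia (0.09 and -0.01; adjusted p = 0.0499) and blood (0.07 and -0.03; adjusted p = 0.00328). An estimated correlation gave, in that order, adjusted p = 0.565, adjusted p = 0.565 and adjusted p = 0.405. No gene passed by limma (0 of 15196), with 119 at an unadjusted p under 0.05. Not passing were 1700105P06Rik (0.94 ± 0.30), Ccl4 (0.83 ± 0.31), Cyp2r1 (0.72 ± 0.28), Zfp389 (0.77 ± 0.31), Tuba1c (-0.91 ± 0.26), Ak8 (-0.57 ± 0.18), Rbm3, a cold-inducible RNA-binding protein (-0.57 ± 0.20), and Insl3 (listed at 0 in estradiol cocaine mice). The small nucleolar RNAs Snora30 (66.7 ± 70.0 and 21.8 ± 31.4 TPM with estradiol in saline and cocaine mice) and Snora17 (23.3 ± 16.4 and 26.1 ± 30.2 TPM with placebo) were listed at 0 in both groups of the other hormone state.

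Of 442 list tests, 133 were called with the preset correlation and 11 with an estimated one. The lists never called, with their smallest adjusted p, were interneurons (adjusted p = 0.0536, cocaine with estradiol), genes of the cocaine literature (adjusted p = 0.0673, ovariectomized against intact), extracellular matrix (adjusted p = 0.0931, sex by cocaine), oligodendrocyte precursors (adjusted p = 0.130, sex in saline), steroid receptors and enzymes (adjusted p = 0.144, sex in saline), opioid and cannabinoid receptors (adjusted p = 0.157, cocaine in females) and the circadian clock (adjusted p = 0.174, estradiol with cocaine).

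The cocaine responses of the 4 conditions were correlated across genes, which are not independent replicates. Pearson r was 0.20 between males and females (Spearman rho 0.22; permutation p = 0.20, adjusted p = 0.40 over 6 pairs) and 0.17 between intact and placebo females (rho 0.24; permutation p = 0.27, adjusted p = 0.405). It was 0.09 between males and placebo females (rho 0.19; permutation p = 0.59, adjusted p = 0.59), -0.10 between intact and estradiol females (rho -0.19; permutation p = 0.45, adjusted p = 0.54), -0.24 between males and estradiol females (rho -0.34; permutation p = 0.04, adjusted p = 0.15) and -0.47 between placebo and estradiol females (rho -0.53; permutation p = 0.05, adjusted p = 0.15). No pair passed the adjustment.

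For differences planted in 100 genes on the real residuals, the median estimate equalled the planted value, so sampling noise was not tested. With independent normal noise, 4-fold cocaine responses were recovered in 95% of genes in males, 94% in females, 92% with placebo and 89% with estradiol. The sex and estradiol interactions had 61% and 71% (residuals 88%, 94%, 96% and 89% in the 4 conditions, and 34% and 29% for the interactions). For 2-fold these were 25%, 38%, 32%, 37%, 11% and 9% (residuals 6%, 15%, 5%, 12%, 0% and 0%). Cocaine over all 4 conditions had 95%. Most 2-fold responses within a condition were missed, as were most 4-fold interactions on the residuals. Sizes between 2-fold and 4-fold were not planted.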

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

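The tests of the library labelled male cocaine 69, of fragment number and treatment as explanations of the least correlated libraries, and of the immediate-early shift over the 4 conditions were chosen only after the result was seen.

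The library labelled male cocaine 69 stood apart from the 4 other male cocaine libraries with Xist at 237 TPM against 0.681 to 1.78 TPM. A mixture of male and female RNA would leave the Y-linked genes at the male share, but the highest of Ddx3y, Eif2s3y, Kdm5d and Uty reached only 0.856% of the mean of the other 4. An exchange with a female library of this series would put male levels there, but 0 of the 30 female libraries had Ddx3y at or above the lowest of the 9 other males. All 9 sex-linked genes lay inside the intact female range and outside the range of the 9 other males, so female RNA under this label, from a wrong label or an exchange outside the 40 libraries, is a candidate explanation. No biological explanation was tested, and the mouse was kept in the group its title gives.

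The 4 libraries with a median correlation under 0.93 carry a high share of ribosomal protein transcripts and a low median gene. Estradiol and cocaine together cannot be the whole cause, since 2 of the 4 belong to other groups, although 2 of the 5 libraries of that treatment are among them (Fisher exact p = 0.069). Within each group, longer transcripts were lower in these libraries, with Spearman rho across genes of -0.62 (male cocaine 67), -0.69 (placebo saline 137), -0.39 (estradiol cocaine 126) and -0.68 (estradiol cocaine 134), so loss of longer transcripts may account for them. The other 36 ranged from -0.54 to 0.45, and 5 of these lay under -0.39. Fewer fragments sequenced cannot be told apart from other causes: 1 fragment was worth more than the median of the other libraries (0.255 TPM) in 2 of the 4, and the depth is known only through this rough measure.

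Over the 4 conditions the immediate-early score was 0.27 higher after cocaine (permutation p = 0.0196, not passing over 5 called lists, adjusted p = 0.0640). The largest part came from estradiol mice (0.64). A varying share of cortical tissue in the punches is a possible explanation, because cortical and immediate-early scores correlate over the 40 libraries (Pearson r = 0.58, permutation p = 1e-04; intact mice 0.71, p = 3e-04; ovariectomized mice 0.44, p = 0.0507). Cortical and striatal scores run opposite (r = -0.44, permutation p = 0.00491), as such a share would give. In intact mice r was -0.36 (permutation p = 0.117, not passing), in ovariectomized mice -0.49 (permutation p = 0.0299, adjusted p = 0.0448). The striatal fall after cocaine was not adjusted for the cortical share, which may explain it. With the cortical score taken out, 73.1% of the immediate-early difference was kept (0.19, 95% interval 0.02 to 0.37, permutation p = 0.0438), which lies between the bounds set for the 2 explanations. Without the 4 libraries, a setting chosen after the data were seen, 76.8% was kept (0.24, 95% interval 0.04 to 0.44, permutation p = 0.0266), above the upper bound of 75%. The cortical share and an effect of cocaine therefore cannot be told apart for the remaining part.

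Of 178 groups of 5 tested, 31 held a library far from the rest. Some libraries recur across measures and some groups were otherwise at 0, so chance was not judged. Male saline 61 had less Drd2 (55.9 TPM, others 139 to 170.0 TPM), the D2 dopamine receptor, and less Pdyn, prodynorphin (136 TPM, others 226 to 236 TPM). Esr1 was high in male saline 63 (3.68, others 0.845 to 1.15 TPM) and placebo cocaine 125 (3.91, others 1.73 to 2.12 TPM). Bdnf was at 7.55 TPM in estradiol cocaine 136 (others 0.393 to 1.57 TPM), and Cartpt at 272 TPM in male cocaine 67 (others 132 to 170.2 TPM). Slc17a7 stood out in female saline 78 (135, others 5.81 to 37.5 TPM), placebo saline 121 (611, others 4.87 to 128 TPM) and estradiol cocaine 136 (339, others 1.77 to 81.1 TPM). The immediate-early score was 0.091 in the library labelled male cocaine 69 (others -0.217 to -0.157) and -1.091 in female saline 77 (others -0.595 to -0.474). Female saline 77 also had a low striatal score, 3.309 against 3.643 to 3.774.

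Y-linked transcripts were found at low level in several females. Female saline 77 had Ddx3y at 3.46 TPM, Eif2s3y at 3.68 TPM, Kdm5d at 1.28 TPM and Uty at 0.915 TPM, all above the 4 other libraries of the group (highest 0.516, 0.515, 0.306 and 0.122 TPM). Female cocaine 70 had Ddx3y at 1.04 TPM and female cocaine 71 Kdm5d at 0.0710 TPM. Estradiol cocaine 134 had Ddx3y at 0.0339 TPM and estradiol saline 130 Kdm5d at 0.0312 TPM, each in a group otherwise listed at 0. In male saline 73, Xist was at 8.02 TPM (others 0.138 to 2.03 TPM), and this library had 17852 genes above 0 (others 15964 to 16379).

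Measures of library quality set further libraries apart. The median gene was at 3.179 in male cocaine 67 (others 4.467 to 4.531), 3.941 in female saline 64 (others 4.455 to 4.566) and 3.193 in placebo saline 137 (others 4.095 to 4.208). Ribosomal proteins held 14.8% in male cocaine 67 (others 4.64% to 5.02%) and 8.60% in female saline 64 (others 4.67% to 4.996%). A single fragment was worth 1.18 TPM in female saline 64 (others 0.207 to 0.424 TPM) and 0.444 TPM in placebo cocaine 125 (others 0.228 to 0.277 TPM). Rn45s, the ribosomal RNA precursor, reached 158382 TPM in placebo cocaine 139 (others 7817 to 25587 TPM).

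In 20 list tests of the difference itself, 7 between the sexes and 13 between estradiol and placebo, camera with the preset correlation called the cocaine response different. With an estimated correlation only 1 was called between the sexes (pituitary hormones) and 0 between estradiol and placebo, and fry called 0 in both, so most of these differences rest on the preset. Between the sexes, females less males, the relative medians were -0.26 for striatal projection neurons, -0.21 for X-inactivation escape, 0.09 for heat shock, 0.64 for choroid plexus and ependyma, 0.64 for cortical excitatory neurons, 0.36 for septal and subpallial neurons and -1.49 for pituitary hormones. Male values include the library labelled male cocaine 69. Between estradiol and placebo they were 0.46 for immediate-early genes, -0.31 for glutamate receptors and scaffolds, -0.62 for the GABA system, 0.35 for neuropeptides, 0.42 for interferon response, 1.42 for oxidative phosphorylation and 1.48 for ribosomal proteins. Oligodendrocytes had 0.62, microglia 0.79, vessel wall and meninges 0.44, choroid plexus and ependyma 1.57, blood 1.54 and pituitary hormones 1.64.

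Other splits of the same libraries show which counts of genes chance can give. For sex in saline mice, the real split gave 5 genes and the highest other 1, with 1 of 100 splits as large, the real one. For sex in cocaine mice, 4 of 100 splits gave as many as the real 5 (highest other 5), so chance is excluded; the 3 others keep the library labelled male cocaine 69 together with 4 of the females. In the 11 other comparisons the real count was 0, which all 100 of 100 splits reach whatever they give, so these splits say nothing about chance. The highest other counts were 0 for cocaine in males, 2 in females, 2 for sex by cocaine, 0 for cocaine with placebo, 0 for estradiol in saline mice, 10 in cocaine mice, 17 for ovariectomized against intact, 0 for cocaine over the 4 conditions and 74 for estradiol over both treatments. For cocaine with estradiol and for estradiol by cocaine they were 5812 and 6024.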

How the results depend on the processing

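Leaving out the 4 least correlated libraries, with or without the library labelled male cocaine 69, list scores without it, the ribosomal protein share as covariate, and sample weights together with that share were tests chosen only after the data were seen. No paired analysis was possible because the groups share no replicate numbers.

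The sex genes and the absence of other calls held under most settings. Of the counts of genes under an alternative, 154 stayed within 1.5 times of the main count, 12 went above 0 from 0, 4 moved and 1 went to 0. For the named genes, 1680 values kept their direction and their side of the threshold, 25 passed it, 5 no longer did and 0 changed direction. The cause of the changes below was not tested unless a value is given.

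With no filter on low values 1 gene passed for cocaine with placebo, 1 for estradiol in saline mice and 1 for ovariectomized against intact. With the animal number run as covariate, ovariectomized against intact has no value, since no run holds both. With array weights 8 genes passed for cocaine in males, 23 for cocaine in females, 1 for sex by cocaine (Ddah2 1.10), 18 for sex in saline, 14 for sex in cocaine mice, 1 for estradiol by cocaine (1700047M11Rik 1.39) and 6802 for ovariectomized against intact. With array weights and the ribosomal protein share the counts were 2, 78, 10 for sex in saline, 27 for sex in cocaine mice, 1 for estradiol by cocaine and 1 for cocaine over all conditions. The 6802 became 0 there, as the median size of those genes' differences went from 0.55 (median SE 0.15) to 0.13 (0.18). With only the 20 samples of the cohort in the fit, 0 genes passed for sex in cocaine mice by limma (300 at an unadjusted p under 0.05). In other splits of the libraries, array weights called as many genes as the real split in 22 of 100 for males (highest other 7058) and 17 of 100 for females (highest other 3012), so chance is not excluded for these counts.

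Camera called 133 of 442 list tests with the preset correlation, 11 with an estimated one and fry 0. For the 46 list results followed, 146 values kept their direction and call, 43 were no longer called and 31 changed direction. All that changed direction concern ribosomal proteins, oxidative phosphorylation, blood or microglia. With quantile normalization ribosomal proteins had 0.00 for estradiol over both treatments. With array weights ribosomal proteins had 0.05 for cocaine in females, 0.04 for sex in cocaine mice, -0.10 for estradiol in cocaine mice and -0.27 for estradiol over both; oxidative phosphorylation had 0.10, -0.12 and -0.22 in the last 3, and blood -0.16 for estradiol in cocaine mice. Without the 4 least correlated libraries oxidative phosphorylation had 0.12 and ribosomal proteins 0.06 for sex in cocaine mice, -0.07 and -0.06 for estradiol in cocaine mice, and -0.12 and -0.14 for estradiol over both; microglia and blood had -0.01 and -0.01 for estradiol in cocaine mice, and oxidative phosphorylation -0.13 for cocaine over all conditions. Without the library labelled male cocaine 69 as well, these values were equal except for ribosomal proteins in sex in cocaine mice (0.08). With the ribosomal protein share as covariate, which is made of the ribosomal protein genes and so cannot test that list, oxidative phosphorylation had 0.07 for sex in saline, 0.05 for sex in cocaine mice, 0.03 for cocaine with placebo and 0.03 for estradiol in saline mice. The direction of these lists thus depends on those settings.

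Without the 4 libraries the correlation of cocaine effects became -0.01 between males and placebo females and 0.01 between intact and estradiol females; without the library labelled male cocaine 69 too, it was -0.05 and 0.01.

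Leaving out 1 library at a time gave 0 to 6105 genes for cocaine with estradiol: 3624 without estradiol cocaine 128, 6105 without 136 and 5898 without 140, and 0 otherwise. For cocaine in males it gave 0 to 1 (Prm1, without male saline 62), for sex in saline 5 to 6 and for sex in cocaine mice 5 to 6. The other 9 comparisons stayed at 0. List calls ranged from 123 to 151. The correlations of cocaine effects ranged from 0.10 to 0.26 (males and females), -0.05 to 0.30 (males and placebo), -0.58 to 0.01 (males and estradiol), 0.03 to 0.24 (intact and placebo), -0.21 to 0.14 (intact and estradiol) and -0.60 to -0.02 (placebo and estradiol). Depth is not recorded, so what it limits is known only through the value of 1 fragment, 0.0721 to 1.18 TPM.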

Other observations

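The genes in the first 2 paragraphs were singled out after their values were seen.

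Transcripts of the choroid plexus and pituitary varied widely between libraries. Ttr, the transthyretin gene of the choroid plexus, averaged 61.3 ± 79.7 TPM in placebo saline mice, where libraries 131 and 137 had 154 and 142 TPM, against 5.34 ± 6.30 TPM in male saline and 22.9 ± 14.3 TPM in female saline mice. Prl, the pituitary hormone prolactin, ranged from 0 to 37.1 TPM in female saline mice and averaged 5.02 ± 10.5 TPM in estradiol cocaine mice, where library 134, among the 4 least correlated, had 23.7 TPM and the others 0 to 1.42 TPM. Gh averaged 7.33 ± 12.7 TPM in male saline mice, where library 61 had 29.7 TPM and the others 0 to 5.65 TPM, and was listed at 0 in estradiol saline mice.

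Some genes passed when libraries were weighted by their quality but not with equal weights on all 40 libraries. In females given cocaine, where 17 of 100 splits of the libraries gave as many weighted calls as the real 23 (highest other 3012), examples are H2-DMb1, an antigen presentation gene (-0.82 ± 0.14), Coro1a, an actin regulator of immune cells (0.48 ± 0.11), Hspa1b, a heat shock protein (1.44 ± 0.27), Nog, a BMP antagonist (0.86 ± 0.17), Adra2a, an adrenergic receptor (0.97 ± 0.21), and Ephx1 (-0.52 ± 0.12). Between the sexes in saline mice examples are Eif2s3x (0.72 ± 0.15) and Jpx (0.78 ± 0.17), both X-linked, and Prl (4.42 ± 0.84), which also passed without female saline 64.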
